A study of Mus musculus with 2 samples.

How the data were processed

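Peritoneal macrophages were collected from female C57BL/6J mice, 6 weeks old, 4 days after an injection of thioglycollate, an irritant that draws macrophages into the peritoneal cavity. Per the labels' protocols, the cells were cultured and either left untreated (mock) or exposed for 6 h to 100 ng/ml lipopolysaccharide (LPS), the bacterial outer membrane component that Toll-like receptor 4 recognises. Total RNA was extracted with Trizol, and 500 ng per sample was turned into biotin-labelled cRNA with a whole-transcript kit and hybridised to Affymetrix arrays, per the labels' protocols. There were 2 samples, 1 per group, so the comparison has no replicates, no test across samples was possible, and no p-values are given. Whether RNA from 1 or several mice went onto each array is not given in the sources used here.

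The table holds the authors' processed expression values on a log2 scale, 1 value per probe set and array. The submitters' processing notes name Affymetrix Expression Console. The summary method, normalization and genome build are not given in the sources used here. The log2 scale was read from the values: the highest, 13.41, would be a linear brightness of 10904 if the values are log2. Read as natural logs it would be 668359, above the scanner limit of 65535. No detection calls or scanner files were used here, so dim values cannot be told from background, and the centring of the arrays could not be checked.

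The table held 10265 probe sets. It did not look like a neutral sample of the transcriptome. Probe sets were present for 7973 of 21900 protein-coding genes (36.4%) in the RefSeq table used for names (GRCm38.p6). Of the 30 cytosolic ribosomal protein genes listed before the data were examined none had a probe set of its own, nor did Actb, Gapdh, Arg1 and Mrc1. The differences between the arrays had a median of -0.11 on the log2 scale over all probe sets. Absolute differences under 0.1 were slightly more frequent (1434 probe sets) than those of 0.1 to 0.2 (1287) or 0.2 to 0.3 (1344). How the rows were selected is not given in the sources used here. Counts and percentiles below therefore describe this table, and a gene without a probe set in it was not analysed here.

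Gene names came from GEO's platform annotation: 7918 probe sets carried 1 gene symbol, 779 several and 1568 none. The gene ID of 7897 of the 7918 was found in the RefSeq table, which changed 0 symbols. Only probe sets with 1 symbol were used for genes, and the log2 values of a gene's probe sets were averaged, giving 7423 genes. Of these, 278 had more than 1 probe set. For the 212 genes with 2, the median gap between the differences of the pair was 0.17. Genes were kept where the higher of their 2 array values reached a floor of 6.06, the median of all probe sets over both arrays, which left 4728 genes. A gene that is dim on both arrays unless it differs passes this floor only through the difference, so list medians that change without the floor are also given without it. The measured quantity was the LPS minus mock difference in log2 units, and genes were described by size alone: at least 2-fold higher or lower is a difference of at least 1 in either direction.

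Before the data were examined, 38 gene lists were fixed from general knowledge of macrophages, together with the rule for named genes. The text names the 15 genes with the largest positive and the 15 with the largest negative difference, 2 to 4 members of each list with the largest absolute difference, up to 2 members per list that differed by at least 2-fold against the list's median, and 14 genes in any case, 10 of which had a probe set of their own. Each list with 3 or more members past the floor was given as the median difference of its members. The 95% interval beside a median comes from binomial order statistics over the members (their range where under 6). The interval describes how firmly the member genes place the median. It is not the range of the members, except in small lists, and not an error between replicate samples. The median was set against 10000 random lists of the same size, drawn from 20 bins of mean expression, and its percentile among them is a description of these 2 arrays. Lists of hepatocyte markers, of markers of other tissues and of FOXO target genes were written after the differences had been seen. The lists share members: Ccl17 and Ccl24, for example, stand among both chemokines and alternative activation genes.

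The calculation was tested on simulated data for the 4728 genes of LPS against mock, with an assumed noise SD of 0.25 log2 units per array. All of 200 genes changed 4-fold passed the 2-fold limit (100.0%), with 14 unchanged genes past it. Of 100 unchanged lists of 15 genes, 3.0% fell outside the central 95% of random lists, and of 100 lists shifted by 0.5, 99.0% lay above it. The simulated noise is an assumption, since the real spread between replicate samples is unknown. Unchanged genes were simulated with noise alone, whereas the real differences over genes past the floor had an SD of 1.27. The share of shifted lists found in the simulation therefore does not carry over to the real lists.

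Alternatives fixed before the data were examined were subtraction of each array's median, quantile normalization, subtraction of a loess of the difference on the mean (span 0.3), no floor, a floor at the 75th percentile, an offset of 32 on the linear scale, the brightest probe set per gene, limits of 1.5-fold and 4-fold, and random lists matched on the mock value. Leaving out the hepatocyte list was added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.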

Results

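Transcript levels were measured on 1 array of untreated mouse peritoneal macrophages (mock) and 1 array of macrophages kept for 6 h with 100 ng/ml LPS, to profile expression with and without LPS. Both arrays gave a value for all 10265 probe sets. The median log2 value was 6.20 on the mock array and 5.95 on the LPS array, and the arrays correlated with r = 0.895 across probe sets, which are not independent replicates. With 1 array per group, the differences below have no replicate check and no error between samples. They compare these 2 samples.

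The largest positive differences were in genes of inflammation and antiviral defence, and 9 of the 15 largest negative ones in liver transcripts. Il1b, which encodes the cytokine interleukin-1 beta, was 258-fold higher on the LPS array (log2 4.32 in mock and 12.33 in LPS). It was followed by Edn1 (endothelin-1, 231-fold), the GTPase Gbp5 (142-fold), the antiviral genes Mx2 (126-fold) and Ifit2 (99.6-fold), Nos2 (inducible nitric oxide synthase, 96.6-fold), Mx1 (93.8-fold), Il6 (89.7-fold), the lymphocyte activation antigen Cd69 (82.7-fold) and the chemokine Ccl4 (81.7-fold). Ifit1, Ptgs2, Ifi213, Cxcl10 and Cmpk2 completed the 15 highest, at 79.8-fold, 76.7-fold, 70.0-fold, 68.2-fold and 66.7-fold. Of the 15 lowest genes, Alb, the gene of serum albumin, was 58.8-fold lower on the LPS array (10.96 and 5.08), Serpina1c had a log2 difference of -4.65, and Cyp2e1, Apoa2, Adh1, Fabp1, Cyp4a12a, Ahsg and Rbp4 were between 12.8-fold and 22.3-fold lower. All 9 stand in the hepatocyte list described at the end. The other 6 were the potassium channel gene Kcnj2 (22.2-fold lower), the cannabinoid receptor gene Cnr2 (20.2-fold), the fatty acid desaturase gene Scd1 (17.7-fold), the chemokine receptor gene Cxcr4 (15.2-fold), the peroxisomal transporter gene Abcd2 (14.7-fold) and the ubiquitin ligase gene Fbxo32 (log2 difference -3.81).

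Among the 4728 genes past the floor, 620 were at least 2-fold higher and 684 at least 2-fold lower on the LPS array. At 4-fold the counts were 318 and 138, at 16-fold 80 and 10, and at 64-fold 15 and 0. The genes past the floor had a median difference of -0.33, and each list median is read against its own matched random lists. Of the genes at least 2-fold apart, 47.5% were higher in LPS. This share was 63.8% after subtraction of the array medians, which shifts every difference by 0.25, and 66.8% after a loess correction, with 409 and 368 genes lower. After quantile normalization it was 50.6%, with 623 genes higher and 608 lower. In 201 of the 620 higher genes the mock value lay below the floor, and in 300 of the 684 lower genes the LPS value did. Such genes include most of the 15 highest and all of the 15 lowest genes named above. Their folds, and so their order, rest on a value that cannot be told from background.

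**Figure D1:**
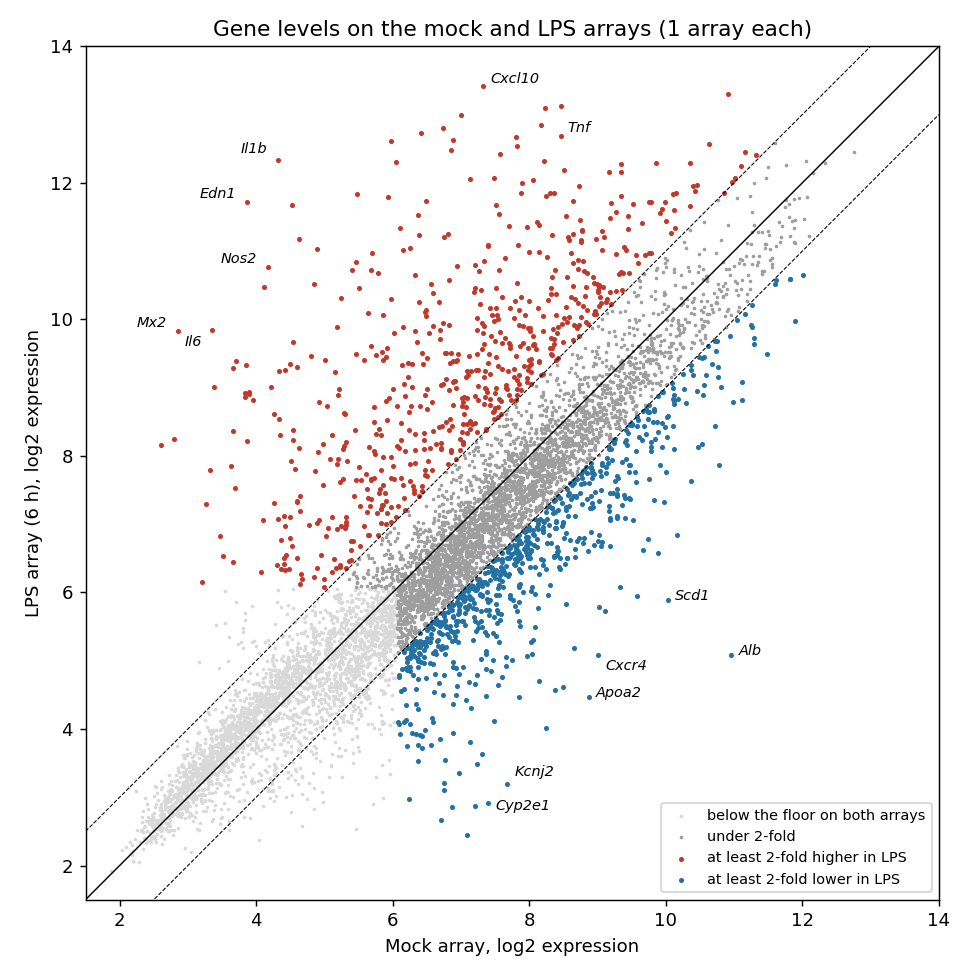
Log2 expression of each gene on the mock array (x axis) and the LPS array (y axis), 1 array each. The solid line marks equal values and the dashed lines a 2-fold difference; 620 genes past the floor lie on or above the upper dashed line and 684 on or below the lower one, with Il1b (4.32 and 12.33) and Alb (10.96 and 5.08) farthest out.

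Cytokine and chemokine transcripts were higher on the LPS array. All 19 inflammatory cytokines past the floor were at least 2-fold higher, with a median difference of 4.87 (interval 2.60 to 5.63 over members), but 13 of them passed it through the LPS value alone. Without the floor, 21 of 24 cytokines were at least 2-fold higher and 3 within 2-fold, with a median of 3.99. Beside Il1b, Edn1 and Il6, the subunit gene Il27 was 50.8-fold higher, Tnf, the gene of tumour necrosis factor, 18.7-fold (8.46 and 12.69), and Il10, an anti-inflammatory cytokine gene, 16.3-fold (3.27 and 7.30). All 17 chemokines past the floor were at least 2-fold higher, with a median of 4.11 (2.40 to 5.08), and without the floor all 19, with a median of 3.93. Ccl4, Cxcl10, Ccl5 and Cxcl2, which attract lymphocytes, monocytes and neutrophils, were 81.7-fold, 68.2-fold, 63.8-fold and 41.5-fold higher. Both medians lay above all 10000 matched random lists, whose central 95% ran from -0.65 to 0.02 for cytokines and from -0.67 to 0.27 for chemokines.

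Interferon-stimulated genes were higher as a group. All 33 antiviral genes with a probe set of their own were at least 2-fold higher, with a median difference of 3.55 (3.26 to 4.67), led by Mx2, Ifit2, Mx1 and Ifit1. All 8 interferon-inducible GTPases past the floor were also at least 2-fold higher, with a median of 4.65 (1.89 to 7.15), 5 of them through the LPS value alone. Without the floor the median of 9 was 4.46, with 1 within 2-fold. Among them Gbp5 was 142-fold, Gbp4 49.5-fold, Gbp3 29.1-fold and Iigp1 28.5-fold higher. These genes belong to families with closely related members, and probe sets that match several of them were left out. Both medians lay above all 10000 random lists. Ifnb1, which encodes interferon beta, was below the floor on both arrays (3.42 in mock and 3.86 in LPS), so its level could not be told from background at 6 h.

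Genes of NF-kappaB signalling and its brakes were higher. All 16 NF-kappaB factors and inhibitors past the floor were at least 2-fold higher, with a median difference of 2.10 (1.65 to 3.25), and 16 of 17 without the floor, with a median of 1.87. Nfkbiz, a nuclear inhibitor-like cofactor, was 21.8-fold higher, the adaptor gene Traf1 had a log2 difference of 3.70, and Nfkbie and Tnfaip3, both negative regulators of the pathway, were 9.96-fold and 9.48-fold higher. Of 20 signalling feedback regulators, 11 were at least 2-fold higher, 1 lower and 8 within 2-fold, with a median of 1.59 (0.46 to 2.39), or 0.96 over 22 without the floor. The cytokine signalling suppressors Socs3 and Socs1 were 25.5-fold and 16.8-fold higher, Cish 10.6-fold and the RNase gene Zc3h12a 7.68-fold higher, while Rgs2, a regulator of G protein signalling, was 3.52-fold lower. Both medians lay above all 10000 random lists. Immediate early transcription factors went both ways: 5 of 14 were at least 2-fold higher, 2 lower and 7 within 2-fold. Nr4a3 was 7.81-fold, Maff 5.86-fold and Ier3 4.70-fold higher, whereas Jun was 4.07-fold and Egr2 2.64-fold lower. The median of 0.53 (-0.42 to 2.23) lay at the 99.6th percentile of random lists, and was 0.46 without the floor.

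Among Toll-like receptors and their adaptors, 6 of 16 were at least 2-fold higher, 1 lower and 9 within 2-fold. Tlr2 was 9.56-fold, the LPS co-receptor gene Cd14 6.02-fold and Tlr3 5.17-fold higher, while Tlr13, a receptor for bacterial ribosomal RNA, was 4.09-fold lower. Tlr4, the signalling receptor for LPS, was 1.97-fold lower (7.49 and 6.51), just within 2-fold. The list median was 0.37 (-0.20 to 1.93), at the 99.1st percentile. Genes of antigen processing for MHC class I were higher, 9 of 12 by at least 2-fold and 3 within it, with a median of 1.77 (0.98 to 2.05). The peptide transporter gene Tap1 was 9.53-fold, the class I transactivator gene Nlrc5 7.97-fold and the immunoproteasome gene Psmb9 4.13-fold higher. Of the 10 MHC class II genes listed, only 2 had a probe set of their own. Of these, H2-Eb1 alone passed the floor, at 10.47 in mock and 10.69 in LPS. Of 14 costimulatory and adhesion molecules, 13 were at least 2-fold higher, with a median of 2.91 (1.38 to 4.23). They included Cd69, Cd40 (53.5-fold), Slamf1 (18.8-fold) and Icam1 (17.3-fold). Of 14 inflammasome and cell death genes, 9 were at least 2-fold higher and 5 within 2-fold, with a median corresponding to 5.66-fold (0.13 to 3.07 in log2 units), or 2.40 in log2 units over 15 without the floor. The sensor gene Nlrp3 was 13.1-fold, Casp4, the mouse caspase-11 gene, 8.86-fold, Nod1 8.42-fold and the caspase-8 regulator Cflar 8.14-fold higher. The medians of the class I, costimulation and inflammasome lists lay above all 10000 random lists.

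Enzymes that make nitric oxide, itaconate and prostaglandin E2 were higher. Of 6 genes of nitric oxide, arginine and itaconate metabolism past the floor, 5 were at least 2-fold higher, with a median difference of 3.22 (0.72 to 6.59), above all 10000 random lists. Without the floor, 5 of 9 were at least 2-fold higher and 4 within 2-fold, with a median of 1.68. Nos2 was 96.6-fold, the itaconate-forming enzyme gene Acod1 29.3-fold (8.23 and 13.10), the arginine transporter gene Slc7a2 15.6-fold, and Gch1, needed for the cofactor of nitric oxide synthase, 5.58-fold higher. Eicosanoid genes went both ways, with 3 of 11 at least 2-fold higher, 2 lower and 6 within 2-fold and a median of -0.32 at the 50.6th percentile, which turned to 0.49 with the floor at the 75th percentile and was -0.35 without the floor. Ptgs2, which encodes cyclooxygenase-2, was 76.7-fold and Ptges, the prostaglandin E synthase gene, 7.62-fold higher, whereas the phospholipase gene Pla2g15 was 3.02-fold and the prostaglandin D synthase gene Hpgds 2.89-fold lower. Of 18 genes of extracellular proteolysis and coagulation, 6 were at least 2-fold higher, 2 lower and 10 within 2-fold, with a median of 0.80 (-0.10 to 2.40) at the 99.8th percentile. Serpinb2 was 20.2-fold, Timp1 14.3-fold and Mmp13 10.4-fold higher, and Thbd, the gene of the anticoagulant thrombomodulin, was 7.40-fold and Mmp19 2.03-fold lower; Mmp19 came within 2-fold under 3 of the alternatives.

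Cholesterol efflux and LXR targets were lower as a group, with a median difference of -1.02 (-1.99 to -0.24), below all but 3 of 10000 random lists. Of 12 members, 6 were at least 2-fold lower, 5 within 2-fold and 1 higher. Scd1 was 17.7-fold, the apolipoprotein gene Apoc1 7.14-fold and Scd2 3.97-fold lower, while Ch25h, which encodes cholesterol 25-hydroxylase, was 27.6-fold higher. Hepatocyte transcripts were lower on the same array, Apoc1 among them, and without that list the median was -0.81, at the 0.24th percentile. Of 14 cholesterol biosynthesis genes, 2 were at least 2-fold lower and 12 within 2-fold, with a median of -0.45 at the 25.6th percentile (-0.40 without the floor). Dhcr7 was 2.56-fold and Sqle 2.33-fold lower, Sqle falling within 2-fold under 2 of the scalings. Antioxidant genes were split: the glutathione synthesis genes Gclc and Gclm were 3.65-fold and 2.74-fold lower, and the superoxide dismutase gene Sod2 and the cystine transporter gene Slc7a11 were 3.81-fold and 3.60-fold higher. Of 9 members 2 were higher and 4 lower by at least 2-fold, and the median of -0.24 lay at the 39.8th percentile, with its sign turned under 1 scaling (highest value 0.0096; -0.29 without the floor).

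Central metabolism and growth lists lay within the central 95% of their random lists. Of 12 glycolysis and HIF targets, 3 were higher, 1 lower and 8 within 2-fold, with a median of -0.30 at the 40.6th percentile that reached 0.0054 under another scaling. Slc2a6, a hexose transporter gene, was 17.8-fold and the glycolysis regulator Pfkfb3 4.95-fold higher, and Bnip3 was 2.13-fold lower but within 2-fold under 4 alternatives. Of 12 genes of the TCA cycle and respiratory chain, 11 were within 2-fold, with a median of -0.29 at the 48.3rd percentile (0.039 after loess), and Idh1, the cytosolic isocitrate dehydrogenase gene, was 3.98-fold and the malate dehydrogenase gene Mdh1 1.40-fold lower. The 18 S phase and mitosis genes had a median of -0.26 at the 79.9th percentile that reached 0.073 under another scaling and was -0.20 without the floor. Ccne1, the cyclin E1 gene, was 6.51-fold and Mki67 2.42-fold higher, and the other 16 were within 2-fold. All 11 genes of the unfolded protein and heat shock response were within 2-fold, with a median of -0.32 at the 39.0th percentile (-0.28 without the floor); Hsph1 was 1.81-fold and Sdf2l1 1.79-fold lower. Only 6 of 31 lysosomal genes listed had a probe set of their own. All 6 passed the floor, with a median of -0.27 at the 34.8th percentile. Tfeb, a transcription factor of lysosomal genes, was 5.08-fold lower and its relative Tfec 2.33-fold higher. Of 20 reference genes, 3 had a probe set, with a median of -0.46 at the 23.1st percentile; Polr2a, the largest subunit of RNA polymerase II, was 2.97-fold lower and Sdha 1.37-fold lower.

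Surface receptors and macrophage identity genes moved in both directions. Of 17 scavenger and phagocytic receptors, 6 were at least 2-fold higher, 1 lower and 10 within 2-fold, with a median of 0.43 at the 97.4th percentile. The oxidised LDL receptor gene Olr1 was 13.5-fold and Clec4e 12.8-fold higher, and Itgb5 was 2.30-fold lower, though within 2-fold under 2 of the scalings. Of 13 chemoattractant and purinergic receptors, 5 were higher and 4 lower, with a median of 0.23 at the 96.8th percentile. Without the floor the median of 18 was -0.11, with 6 higher and 5 lower. Hcar2, Gpr84 and Ccrl2 were 20.5-fold, 12.5-fold and 7.98-fold higher, and Cxcr4 and S1pr1 were 15.2-fold and 7.15-fold lower. Among 11 general macrophage markers, Cebpa, a myeloid transcription factor gene that liver also uses, was 12.3-fold and Pparg 5.05-fold lower, whereas Cd14 was 6.02-fold and Irf8 3.32-fold higher. The list had 3 genes higher and 2 lower, with a median of 0.41 at the 93.5th percentile. Of 6 large resident peritoneal macrophage markers, Timd4 was 3.72-fold higher, and Itga6 and Cd93 were 2.73-fold and 2.06-fold lower, Cd93 within 2-fold under 2 of the scalings; the median was -0.51 at the 14.1st percentile, or -0.64 at percentile 6.10 without the floor. Of 7 alternative activation genes, 3 were higher, Ccl17 by 9.41-fold and Ccl24 by 4.48-fold among them, and 2 lower, Pparg and Egr2. Their median of -0.02 lay at the 84.2nd percentile and turned positive under other scalings. Of 4 complement genes past the floor, the factor B gene Cfb was 9.49-fold higher and 3 were within 2-fold, among them C5ar1 (1.35-fold higher), with a median of 0.30 at the 79.4th percentile.

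**Figure D2:**
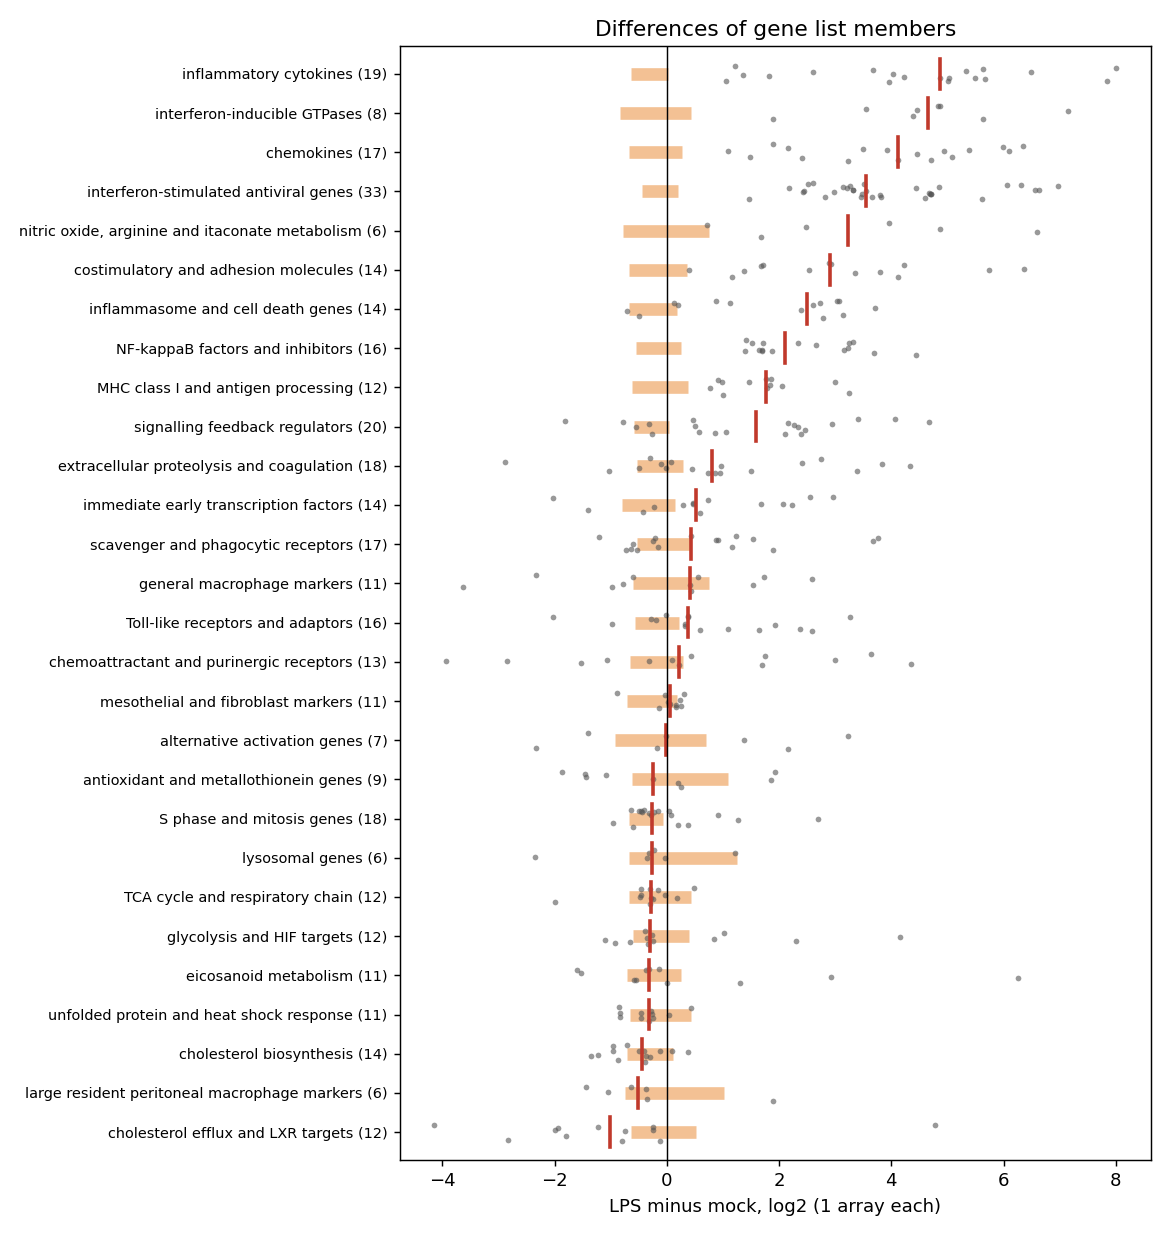
LPS minus mock difference (log2, x axis) of the members past the floor (grey points, number in brackets) of each gene list fixed beforehand with at least 6, with the list median (red line) and the central 95% of medians of 10000 matched random lists (orange bar). Cytokines (4.87), interferon-inducible GTPases (4.65) and chemokines (4.11) lie farthest above their random lists, and cholesterol efflux and LXR targets (-1.02) lie below theirs.

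Few markers of other blood cells passed the floor, but many had no probe set of their own and were not analysed here. A probe set was present for 8 of 17 B cell, 5 of 22 T and NK cell and 7 of 18 neutrophil markers. It was present for 5 of 18 markers of mast cells, basophils and eosinophils and 5 of 15 of dendritic cells. Of 3 B cell markers past the floor, Cd79b and Cd22 were 1.53-fold and 1.45-fold lower, with a median of -0.54 at the 37.5th percentile; without the floor the median was 0.0078. None of the 5 T and NK cell markers with a probe set reached the floor, and erythroid and platelet markers had no probe set of their own. The neutrophil list had 3 members past the floor, with a median of 0.55 at the 90.4th percentile (0.20 without the floor). Lcn2 was 33.0-fold higher, while Csf3r and Mmp9 were 1.46-fold and 1.36-fold higher. Hdc, the histamine-forming enzyme gene in the mast cell list, was 18.6-fold higher while Cpa3, a mast cell protease gene, was at 6.18 and 5.94. In the dendritic cell list 3 of 4 genes were at least 2-fold higher, Ccl22 by 11.3-fold, Irf8 by 3.32-fold and Ccr7 by 3.23-fold, with a median of 1.71 at the 98.8th percentile (1.69 over 5 without the floor), or at the 88.8th with lists matched on the mock value. All 11 mesothelial and fibroblast markers were within 2-fold, with a median of 0.07 (-0.15 to 0.25) at the 94.5th percentile. Among them Lrrn4 was 1.86-fold lower, and the fibroblast gene Dcn was at 10.48 and 10.79.

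Liver transcripts separated the arrays. Of 34 hepatocyte markers past the floor, a list written after the differences had been seen, 29 were at least 2-fold lower on the LPS array. Another 4 were within 2-fold and 1, the hepcidin gene Hamp, was 2.52-fold higher. Hamp passed the floor through the LPS value alone (5.41 in mock and 6.75 in LPS). The median difference was -2.83 (-3.62 to -2.41), and -2.08 without the floor, which 29 of the 34 passed through the mock value alone. It is not set against random lists, since the list was prompted by genes it holds. Counting members below the floor, 55 of the 62 hepatocyte markers in the table were at least 2-fold lower in LPS. Without the hepatocyte list, 619 genes were at least 2-fold higher and 655 lower. That step removes only the listed genes, so other genes that liver expresses remain in both counts. Of 10 markers of pancreas, intestine and kidney and 5 of muscle, nerve and skin in the table, none was at least 2-fold lower, but 13 of the 15 were below the floor on both arrays. Syn1 and Mbp, which passed it, were 1.33-fold and 1.28-fold lower.

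**Figure D3:**
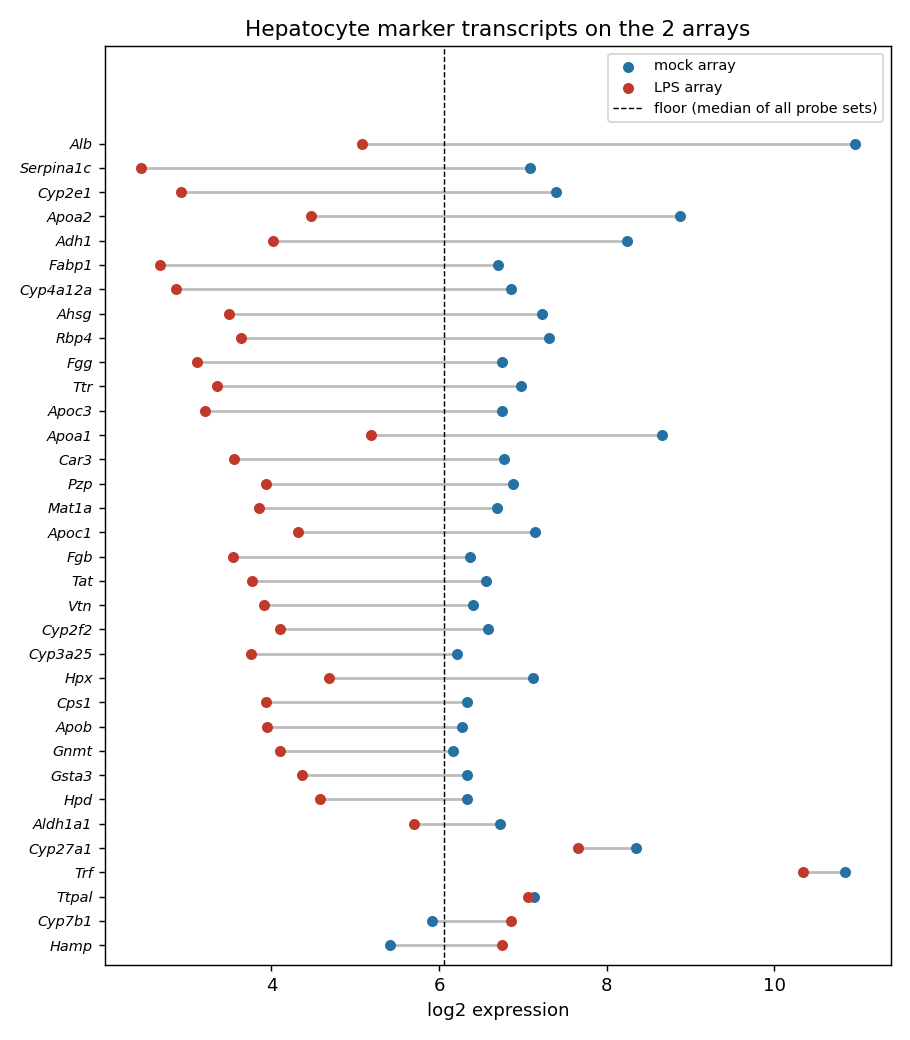
Log2 expression (x axis) of the 34 hepatocyte markers past the floor on the mock array (blue) and the LPS array (red), 1 array each, with the floor of 6.06 as a dashed line. For 29 of the 34 the mock value exceeds the LPS value by at least 1, and Alb is farthest apart at 10.96 and 5.08.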

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

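Probe sets without a gene of their own took no part in the gene comparisons, and some of them were higher and others lower on the LPS array than on the mock array, which is why they are given here. No test was run. Of 451 probe sets past the floor with no gene symbol, 48 were at least 2-fold higher on the LPS array and 52 lower, from -5.32 to 5.18 on the log2 scale. Among the lowest, 9 neighbouring probe sets, 10513420 to 10513512, differed by -5.28 to -4.16. They were chosen after their values were seen and no gene was assigned to them. Of 239 with several gene symbols, 45 were at least 2-fold higher and 26 lower, from -4.26 to 6.15. For scale, of the 4728 genes past the floor 620 were at least 2-fold higher and 684 lower.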

How the results depend on the processing

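Leaving out the hepatocyte list was chosen after the differences had been seen. With 1 array per group no replicate could be left out, and no spread between samples is known. No paired analysis was possible because each group holds a single sample. The count of genes at least 2-fold higher was 620 and stayed within 1.5 times of that under the alternatives tried except the 4-fold limit (318). The count of lower genes, 684, depended on the scaling and on dim genes. It was 608 after quantile normalization, 409 after subtraction of the array medians and 368 after loess. With the floor at the 75th percentile it was 372, with an offset of 32 it was 422, and it was 1525 at 1.5-fold and 138 at 4-fold. The share of higher among these genes was 58.1% with the higher floor, 34.0% at 1.5-fold and 69.7% at 4-fold. List medians moved outside their intervals in these cases. Loess gave 2.09 for MHC class I, -0.098 for cholesterol biosynthesis and -0.23 for reference genes. It turned the TCA cycle list to 0.039. Subtracting medians gave -0.0347 for the TCA cycle list and -0.21 for reference genes, and mesothelial and fibroblast markers reached 0.32, or 0.39 with loess. Without the floor, B cell markers turned to 0.0078 and neutrophil markers fell to 0.20, since more members entered. The causes of the other shifts were not tested. Within their intervals, the median of chemoattractant and purinergic receptors turned to -0.11 without the floor, and that of eicosanoid metabolism to 0.49 with the floor at the 75th percentile. Of 1106 values of the 158 named genes under alternatives, 0 turned sign from a difference of at least 2-fold, 17 came within 2-fold and 4 passed it. The hepatocyte list's median was -2.08 without the floor, -3.85 with the higher floor and -1.55 with the offset. Matched on the mock value, scavenger receptors lay at percentile 99.9 and general macrophage markers at 99.8 of random lists, above the central 95%, and dendritic cell markers at 88.8, within it. Without the hepatocyte list, scavenger receptors lay at 97.6, against 97.4 with it. None of them is in that list, so only the random lists changed. Signal over background was not known for dim genes, which limits every fold that rests on a value below the floor.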

Other observations

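The tests and gene groups in this part were chosen after the differences had been seen. Genes sharing a symbol prefix were scanned as 74 families of at least 8 genes past the floor, of which 10 lay above and 8 below the central 95% of matched random lists, where 3.7 would be outside by chance. Beside chemokines and interleukins, the Schlafen genes, which restrict cell growth and viruses, were at least 2-fold higher in 8 of 8, with a median difference of 3.37 (3.39 to 3.70 under the 3 other scalings). Slfn4 was 37.8-fold and Slfn1 26.2-fold higher. Genes with the prefix Ifi were higher in 8 of 9, with a median of 4.71 (4.50 to 4.97 under other scalings). They include the DNA-sensing Ifi200 cluster, where Ifi206 was 51.5-fold and Ifi214 44.0-fold higher but Ifi207, already at 11.50 in mock, was 1.65-fold higher. The 10 PARP genes had a median of 2.06 (2.05 to 2.38 under other scalings) but divided: Parp14, Parp9, Parp8, Parp12, Parp10 and Parp11 were 11.2-fold, 6.87-fold, 5.94-fold, 5.49-fold, 5.03-fold and 3.43-fold higher, while Parp1, the DNA repair enzyme, was 2.04-fold and Parp2 1.71-fold lower.

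The families below the central 95% had no common theme that was tested, and those given here were not chosen by a rule and are not all of the 8. Of 14 Vps genes of endosomal sorting, 5 were at least 2-fold lower and 0 higher, with a median of -0.82 at the 0.28th percentile (-0.72 to -0.50 under other scalings). The 9 Myo genes (myosins) and the 12 with the prefix Tbc had medians of -0.90 and -0.85, at percentiles 0.295 and 0.39, and their medians kept their sign under the other scalings. Probe sets named for microRNAs (prefix Mir) had a median of 0.34 over 21 (0.58 to 0.66 under other scalings), and the one named Mir155 was 33.0-fold higher (3.89 and 8.94). Whether they read mature or primary transcripts was not tested. Of the other families above the central 95%, those with the prefixes Gm and Snord had medians of 0.48 and 0.23. Not all of the 10 above it are described.

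Liver transcripts were higher on the mock array than on the LPS array, with Alb at 10.96 and 5.08. Hepatocyte RNA in the mock sample would raise most hepatocyte genes together, those that had not prompted the list included: without members whose values had been seen when it was written, and without the 15 lowest genes, 45 of 52 (86.5%) were at least 2-fold lower in LPS with no floor applied, against 11.3% of all genes. Liver material carried over at harvest, or mixed in at a later step, is therefore a candidate explanation, with the limit that the selection of rows in the table could have favoured hepatocyte genes that differed. In mock, 13 markers of other tissues lay at or above the floor and had room to be lower (the 11 mesothelial and fibroblast markers, Syn1 and Mbp). Their median difference was 0.0346 (-0.35 to 0.23), and 0 were at least 2-fold lower. These values argue against a loss on the LPS array of all tissue-specific transcripts above the floor. They cannot speak for dim transcripts, since values below the floor could not be told from background. A decrease of the liver transcripts within macrophages stays open and was not tested, because sample and treatment coincide on 1 array each.

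Another pattern is the lower median of the list of cholesterol efflux and LXR targets, which liver RNA in the mock sample could also produce. The list joins genes of sterol efflux and LXR targets, so its median does not speak for LXR targets alone. After removal of the 6 members that liver is known to express strongly (Scd1, Apoc1, Rxra, Abca1, Nr1h3 and Lpcat3), the median of the 6 left was -1.02, at the 0.21st percentile of random lists. Because Abca1, Nr1h3 and Lpcat3 had hardly differed, their removal offset that of the 3 lower genes; with Scd1, Apoc1 and Rxra alone removed, the median of the 9 left was -0.75, at the 0.97th percentile. The first removal took 3 members from each side of the median and so could not move it, and that value decides nothing. The second value argues against liver RNA as the whole source of the list's shift. It leaves open how much of the difference in Scd1, Apoc1 and other genes that both cell types use, such as Cebpa and Idh1, came from either.

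The cause of the excess of lower over higher genes was not tested. Subtraction of the array medians adds 0.25 to every difference, so the fall in lower genes to 409 follows from the shift itself. After loess the count was 368, and after quantile normalization it was 608 against 623 higher. The difference varied with brightness: over all genes, the medians of 5 groups of equal size were 0.13, -0.26, -0.38, -0.31 and -0.21 from dim to bright, and past the floor they were -0.53, -0.34, -0.33, -0.24 and -0.19. An offset between the arrays, a trend with brightness, the selection of rows and a true excess of lower transcripts were not told apart.

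Among the lowest genes, Fbxo32 and Sesn1 (10.8-fold lower) are textbook targets of FOXO transcription factors, which raised the hypothesis that FOXO targets were lower together. It was tested on a list written without Sesn1, Fbxo32 and Cxcr4, on the same arrays. The list as first written had 23 members past the floor and a median of -0.94, at the 0.03rd percentile. Then 4 of them whose values had been seen were taken out. They were S1pr1 (7.15-fold lower), Bnip3 (2.13-fold lower), Cat (2.11-fold lower) and Sod2, which went the other way (3.81-fold higher). Of the 19 members left, 8 were at least 2-fold lower, 11 within 2-fold and 0 higher, with a median of -0.81 (-1.53 to -0.09) at the 0.535th percentile. The median ran from -0.88 to -0.55 under the other scalings. Without the floor, 22 members had a median of -0.62 at percentile 1.2. Among the members within 2-fold, Cited2 and Sesn3 were 1.82-fold and 1.60-fold higher. Tsc22d3, Klhl24, Insr and Gadd45a were 6.12-fold, 3.41-fold, 3.20-fold and 2.90-fold lower. Several of these genes also answer to glucocorticoids or are expressed in liver, so lower FOXO activity is only one candidate explanation.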
